A study of Mus musculus with 6 samples.

How the data were processed

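RNA was sequenced from primary mouse liver sinusoidal endothelial cells, in 3 control and 3 stretch libraries made with a TruSeq kit. Groups were taken from the sample labels. Replicate numbers 2 and 4 occur in both groups, but no label says that a number marks a shared isolation.

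The raw counts per gene were deposited by the authors for all 6 libraries, and the submitters' processing notes name TopHat2 2.1.0, featureCounts and edgeR with the GRCm38 (mm10) genome build. Which tool made which values, the annotation, filters and strand setting are not given in the sources used here, so reads of overlapping or antisense genes cannot be told apart. The deposited RPKM values were made by the authors per kilobase of coding length, and in each library the total they were divided by was between 7.38% and 8.87% above the sum of the gene counts. The authors' comparison table holds log2 fold changes and mean log2 CPM values, a score (the likelihood ratio statistic) and a p-value with its FDR, per the file headers. Positions are those of the deposited table. Of 23337 gene symbols 20755 (88.9%) matched the reference gene table by name. The count table lists 0 mitochondrial genes, so the share of mitochondrial counts was not analysed here.

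Counts from 1 to 10 were even in 67.2% to 69.8% of cases, against 49.6% to 50.9% for counts of at least 1000. Intervals from counts cover counting error only, and are too narrow where both mates of a read pair were counted.

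The deposited counts were tested with edgeR 4.0.16 in R 4.3.3, using TMM scaling, filterByExpr with default settings and the quasi-likelihood F test for group, with Benjamini-Hochberg adjustment over the 14222 genes tested of 23337 (4781 had no count). A gene was called at an adjusted p under 0.05 with no minimum fold. The SE of a log2 fold change was the estimate divided by the square root of F. Means and SDs are of TMM-scaled CPM. The common biological coefficient of variation was 0.12. TMM factors lay between 0.953 and 1.045, and between 16489 and 16818 genes had a count in a library.

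The 28 gene lists, the test, the alternatives and the naming rule were written before the data were examined. The rule names the 10 called genes with the largest log2 fold change in each direction, among genes with a mean of at least 1 log2 CPM and group CPM ranges that do not overlap (2819 higher and 2979 lower were eligible, and 1 predicted gene was skipped). It also names up to 4 called members with the smallest p in each list, or 2 members where fewer than 2 were called, and 5 genes whatever their result: Cxcl1, Hes1, Hey1, Notch1 and Piezo1. Lists with at least 5 tested members were compared with all other genes by camera in limma 3.58.1 on log2 CPM (prior count 2), with a preset correlation of 0.01 and Benjamini-Hochberg adjustment over 26 lists. Older symbols were used where the table has them (Fam38a, Fam38b, Jub, Sc4mol, Darc, Emr1 and Beta-s), and Muc16, Ly6g and Hbb-bt were not found. F8, Vwf, Acta2, Col1a1, Col1a2 and Col3a1 are each in 2 lists.

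Single values per library were compared by exact two-sided permutation tests. The 10 most abundant genes took 8.19 ± 0.64% of counts in control and 7.79 ± 0.34% in stretch libraries (SD, n = 3 per group; exact permutation p = 0.4). The ribosomal precursor Rn45s took 2.72 ± 0.65% and 2.90 ± 0.47% (SD, n = 3 per group; exact permutation p = 0.7). Pearson's r of log2 CPM across genes was between 0.985 and 0.991 within groups, and genes are not independent replicates.

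The alternatives were RLE and upper-quartile factors, library size only, no filter, a filter of 1 CPM in 3 samples, DESeq2 1.42.0, limma-voom, the edgeR exact test, robust dispersion, glmTreat against a fold of 1.2, the replicate number as a block, and each library left out in turn. For the lists they were an estimated correlation, fry, library size only, RLE factors, no filter, the block and each library left out. Counting the called members of each list without stretch replicate 1 was added after the data were seen.

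The steps were tested on simulated data for the comparison of stretch with control: counts for 14222 genes with 200 changed. Of the changed genes 58% were recovered at 1.5-fold, 70.7% at 2-fold and 91.8% at 4-fold, and 11 unchanged genes were called. The data had far more called genes, 6261, and the adjustment is less strict then, so these rates check the steps and do not describe recovery in the data.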

Results

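Gene expression was measured by RNA sequencing in primary sinusoidal endothelial cells of mouse liver, the fenestrated cells that line the hepatic capillaries. The cells were purified with antibody-coated magnetic beads, grown on collagen IV and deprived of serum. They were then either left static (control) or exposed to 4% cyclic stretch at a frequency of 1 Hz on a Flexcell device, which deforms the membrane the cells grow on. How long the stretch lasted is not given in the sources used here. The 6 libraries comprised control replicates 2, 3 and 4 and stretch replicates 1, 2 and 4. Total gene counts were between 48948948 and 57923937 in control and between 58503669 and 68489956 in stretch libraries. Totals were higher in each stretch library than in each control library (n = 3 per group; exact two-sided permutation p = 0.1, the smallest that 3 against 3 can give).

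The comparison asked which transcripts differ between stretched and static sinusoidal endothelial cells. Stretched cells had higher levels of most immediate early and NF-kB feedback genes tested, and of 12 of 21 chemokines and cytokines and 13 of 22 contractile and actin genes. They had lower levels of most cholesterol synthesis genes, of several sinusoidal endothelial markers and of some interferon-induced genes. As whole lists these passed with a preset correlation between genes and did not pass with an estimated correlation. That setting has little power with so few libraries. With fry, which asks whether a list's genes move on balance in 1 direction, each of these lists passed (adjusted p up to 0.0296, for interferon response). Fry does not compare a list with other genes, of which many changed here as well. The chemokine gene Ccl2, whose product recruits monocytes, rose 2.61-fold, from 991 ± 138 to 2585 ± 441 CPM (counts normalised to the TMM-scaled library size; mean ± SD, n = 3 per group). Maf, a transcription factor of sinusoidal endothelium, fell 4.49-fold, from 220 ± 18.6 to 49.01 ± 11.7 CPM (mean ± SD, n = 3 per group). Transcripts typical of hepatocytes were also higher in the stretch group, most of all in stretch replicate 1, and macrophage transcripts were higher in the 3 stretch libraries.

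Of 14222 genes tested with edgeR's quasi-likelihood test, 6261 passed a Benjamini-Hochberg adjusted p of 0.05, 3040 higher and 3221 lower after stretch. The counts of called members in each list below are to be read against these shares. The changes were mostly small: the median absolute log2 fold change of the called genes was 0.41, and 654 of them changed at least 2-fold (350 higher and 304 lower). The CPM ranges of the groups did not overlap for 7945 genes (55.9%), where chance gives 10%. The first principal component of log2 CPM held 51.9% of the variance and separated the groups. With library sizes alone as scaling, 6390 genes were called, 2091 higher and 4299 lower, so that 32.7% were higher against 48.6% with TMM. Against a minimum change of 1.2-fold (glmTreat), 2537 genes were called. Without stretch replicate 1, 5358 genes were called, and the 5165 of these that were also called with all libraries had the same direction in both.

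**Figure D1:**
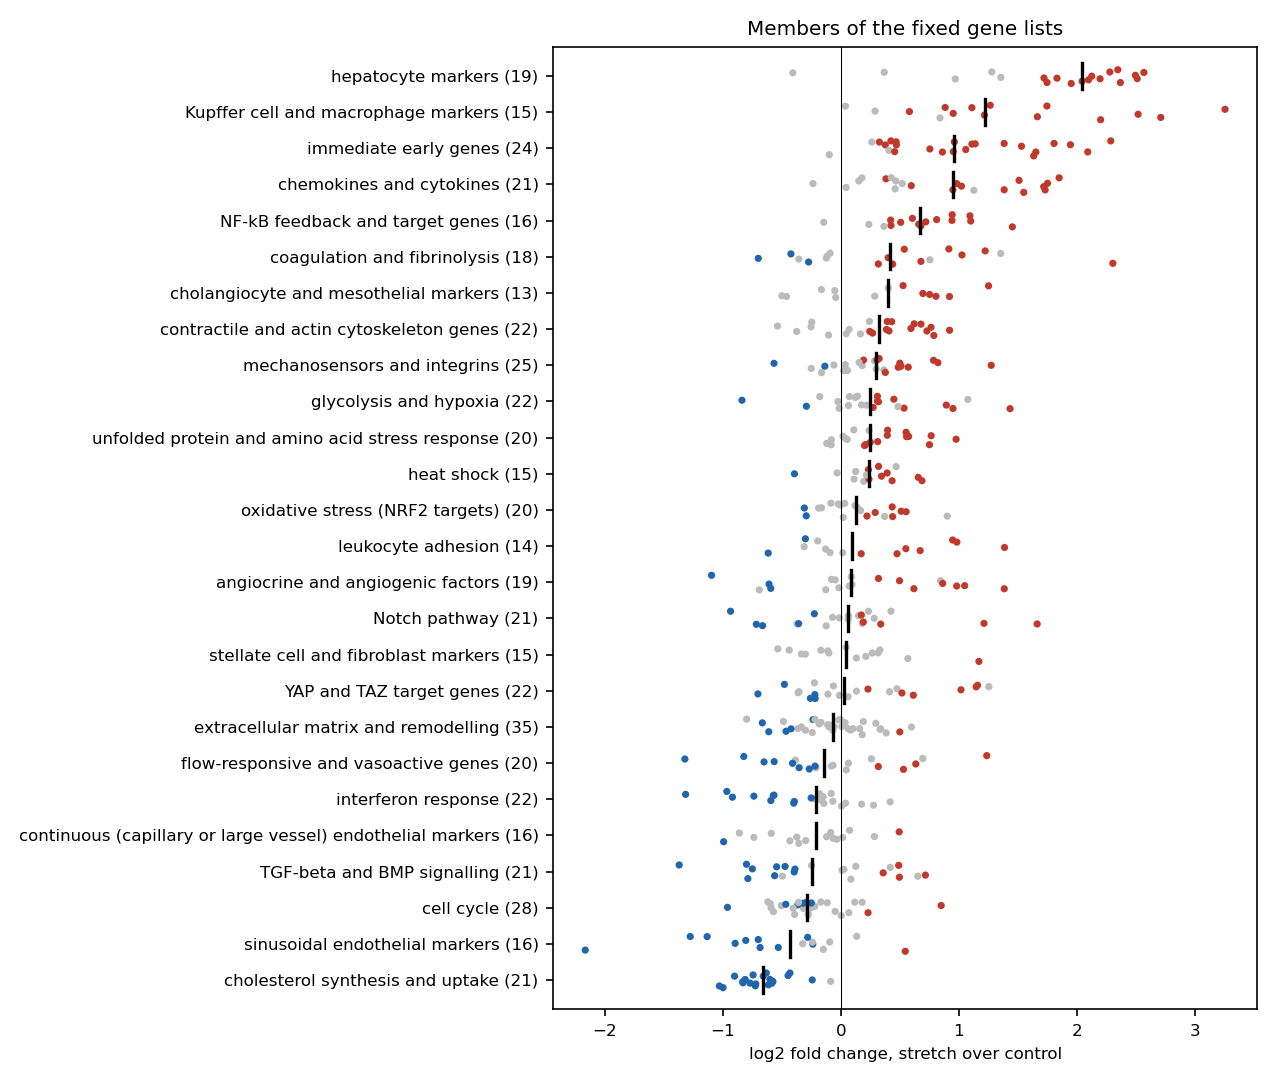
Log2 fold change (stretch over control) of each tested member of the fixed gene lists, with the number of tested members in brackets. Red points passed the test higher, blue points passed it lower, grey points did not pass, and the black bar is the list's median, which ranges from -0.66 for cholesterol synthesis and uptake to 2.04 for hepatocyte markers.

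Among the genes with the largest called increases were 3 whose change was similar with and without stretch replicate 1. Kcne3, a potassium channel subunit (chromosome 7, 100176670 to 100184869), rose by a log2 fold change of 2.61 ± 0.26 (SE; edgeR adjusted p = 0.000147). Spry4, a feedback inhibitor of receptor tyrosine kinase signalling (chromosome 18, 38586265 to 38601268), rose from 41.1 ± 7.13 to 249.7 ± 63.3 CPM (log2 fold change 2.60 ± 0.20). Mycn, a MYC family transcription factor (chromosome 12, 12936093 to 12941836), rose from 1.51 ± 0.16 to 8.14 ± 2.24 CPM (log2 fold change 2.42 ± 0.21). The other 7 of the top 10 were Igfbp1, Creb3l3, Fga, Fgb, Cyp3a11, Abcc2 and Cps1, all known from hepatocytes, with log2 fold changes between 2.35 and 2.75. Their levels were highest in stretch replicate 1, and without it the log2 fold change was 1.58 for Igfbp1, 1.37 for Creb3l3, 1.01 for Fga, 1.14 for Fgb, 0.91 for Cyp3a11, 1.47 for Abcc2 and 1.16 for Cps1. Fga then no longer passed (edgeR adjusted p = 0.0658). The edgeR calls were also lost for Cps1, Creb3l3, Cyp3a11, Fga and Fgb without control replicate 2 (adjusted p = 0.0639, 0.0661, 0.0802, 0.108 and 0.0800) and without control replicate 3 (adjusted p = 0.0521, 0.0523, 0.0819, 0.0933 and 0.0714). Without control replicate 4 the edgeR call of Cyp3a11 was lost (adjusted p = 0.0809). With limma-voom none of these 7 genes passed, with adjusted p between 0.0554 for Igfbp1 and 0.168 for Cyp3a11, and with robust dispersion they ranged from 0.0587 for Abcc2 to 0.133 for Fga.

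The largest called decreases were in genes of varied function. Pde7b, a cAMP phosphodiesterase (chromosome 10, 20398004 to 20725068), fell 7.97-fold, from 40.7 ± 4.44 to 5.10 ± 0.41 CPM, with a log2 fold change of -2.99 ± 0.10 (edgeR adjusted p = 1.19e-05). Clec14a, an endothelial C-type lectin family protein (chromosome 12, 58264720 to 58269258), fell 6.69-fold from 252.9 ± 58.5 CPM. Cyp26b1, which degrades retinoic acid, fell 5.86-fold, and Tnfsf10, which encodes the death ligand TRAIL, fell 5.98-fold. Gab3, Epor (the erythropoietin receptor) and the interferon-inducible GTPase gene Iigp1 fell 4.35-fold, 4.32-fold and 3.86-fold. Ctsq, a placental cathepsin gene (chromosome 13, 61035038 to 61040597), had 73, 427 and 523 counts in control replicates 2, 3 and 4 and 0, 0 and 1 in stretch replicates 1, 2 and 4. Its ratio of control to stretch was 1130, with a 95% exact binomial interval of 202 to 44600 that covers counting error only (edgeR adjusted p = 0.000423).

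Chemokine genes and NF-kB genes rose together. Of 21 tested chemokines and cytokines, 12 rose, 0 fell and 9 did not pass (12 and 0 adjusted over the list alone). Besides Ccl2 (log2 fold change 1.38 ± 0.14), the clearest were Il1a, encoding interleukin-1 alpha (1.72 ± 0.17), the macrophage growth factor Csf1 (0.95 ± 0.11) and the cytokine Lif (1.02 ± 0.12). Csf1 increased from 410.1 ± 63.0 to 792 ± 71.4 CPM. Cxcl1, a neutrophil chemoattractant chosen before the data were examined (chromosome 5, 90891245 to 90893115), rose from 6.49 ± 0.93 to 12.8 ± 4.07 CPM (log2 fold change 0.98 ± 0.21, edgeR adjusted p = 0.00606). The list was higher than other genes by camera (adjusted p = 0.000178), but not with an estimated correlation (adjusted p = 0.347). Of the 16 NF-kB feedback and target genes, 13 rose, 0 fell and 3 did not pass (14 and 0 adjusted over the list alone). Nfkbia, which encodes the inhibitor IkB alpha, reached a log2 fold change of 0.94 ± 0.07, Relb 0.72 ± 0.06, Nfkb2 0.68 ± 0.05 and the apoptosis inhibitor Birc3 0.61 ± 0.05. Camera called this list higher (adjusted p = 1.54e-06; adjusted p = 0.347 with an estimated correlation). Both lists moved together with the macrophage markers, whose summed level was 124 ± 11.01 CPM in control and 177 ± 26.95 CPM in stretch libraries.

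Leukocyte adhesion and clotting genes changed in both directions. Among 14 adhesion genes 7 rose, 2 fell and 5 did not pass (7 and 4 adjusted over the list alone). E-selectin (Sele) increased 2.61-fold, Vcam1 1.59-fold, the hyaluronan receptor Cd44 1.93-fold and Mcam 1.98-fold, while the 2 that fell, Jam3 and Cd99l2, had log2 fold changes of -0.62 and -0.30. In the coagulation and fibrinolysis list of 18 genes, 9 rose, 3 fell and 6 did not pass (9 and 3 adjusted over the list alone). The urokinase receptor gene Plaur rose 2.33-fold, the protease inhibitor gene Tfpi2 2.04-fold and the protein C receptor gene Procr 1.36-fold. F8, Entpd1 and Tfpi were the 3 that fell. Neither list differed from other genes by camera (adjusted p = 0.319 and 0.114), although by fry, which asks whether a list's genes move on balance in 1 direction, each passed as higher (adjusted p = 0.0233 and 0.0209). Over all alternatives the adjusted p of each of the 2 lists reached 0.608, with an estimated correlation.

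Immediate early genes, which respond to growth factor and mechanical signals without new protein synthesis, were mostly higher. Of 24 members 21 rose, 0 fell and 3 did not pass (22 and 0 adjusted over the list alone). Maff rose 3.10-fold, the AP-1 subunit Fosl1 3.14-fold, Atf3 2.89-fold and Ier2 2.61-fold, with log2 fold changes of 1.63 ± 0.07, 1.65 ± 0.09, 1.53 ± 0.09 and 1.38 ± 0.08. Camera placed the list above other genes (adjusted p = 5.93e-10; adjusted p = 0.347 with an estimated correlation). Of 22 contractile and actin cytoskeleton genes, 13 rose, 0 fell and 9 did not pass (13 and 0 adjusted over the list alone). Actg1 and Actb, the cytoplasmic actins, rose 1.89-fold and 1.51-fold, caldesmon (Cald1) 1.66-fold and non-muscle myosin heavy chain Myh9 1.6-fold. The smooth muscle actin gene Acta2 had a log2 fold change of 0.04 ± 0.25. This list was called higher by camera as well (adjusted p = 0.000524; adjusted p = 0.347 with an estimated correlation).

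Of 25 mechanosensors and integrins, 11 rose, 2 fell and 12 did not pass (12 and 3 adjusted over the list alone). Itgb3 rose 1.77-fold, Itgav 1.72-fold, vinculin (Vcl) 1.49-fold and integrin-linked kinase (Ilk) 1.41-fold. The 2 that fell were Itga1 and Ptk2, of which 1 passed without stretch replicate 1. The mechanically gated channel Piezo1, listed under its older symbol Fam38a (chromosome 8, 122481698 to 122551329), was at 371 ± 12.6 CPM in control and 381 ± 5.82 CPM in stretch libraries, with a log2 fold change of 0.04 ± 0.05 (edgeR adjusted p = 0.535). Its sign changed with library sizes alone as scaling (log2 fold change -0.05). Camera called the list higher (adjusted p = 0.00696; adjusted p = 0.429 with an estimated correlation). Target genes of the mechanosensitive coactivators YAP and TAZ split: of 22, 6 rose, 5 fell and 11 did not pass (6 and 5 adjusted over the list alone). Both shares are near those over all genes tested. Cyr61 rose 2.21-fold, Gadd45b 2.23-fold and the kinase gene Nuak2 2.02-fold, whereas Ajuba, listed as Jub, fell 1.63-fold. The YAP and TAZ list as a whole did not stand apart (camera adjusted p = 0.677).

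**Figure D2:**
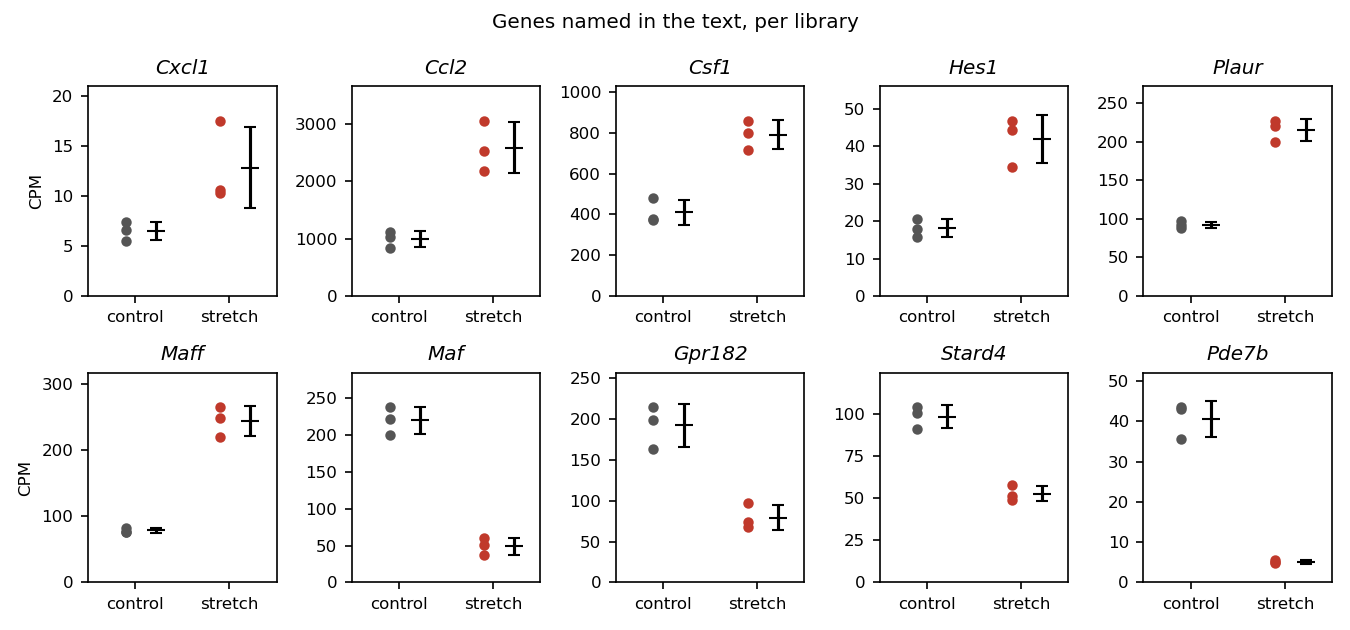
Level in CPM (TMM-scaled) of 10 genes named in the text in each control library (grey points) and stretch library (red points), with the group mean (short bar) and SD (error bar, n = 3 per group). Ccl2, for example, had a mean of 991 in control and 2585 in stretch libraries, and Pde7b of 40.7 and 5.10.

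Notch pathway genes went both ways, in shares near those over all genes tested. Hes1, a transcriptional repressor induced by Notch and other signals (chromosome 16, 30065357 to 30067796), rose from 18.1 ± 2.36 to 41.9 ± 6.46 CPM, a log2 fold change of 1.21 ± 0.13 (edgeR adjusted p = 0.000197). Hey1, another Notch target (chromosome 3, 8663359 to 8667038), was scarce, with 0.57 ± 0.18 CPM in control and 0.56 ± 0.17 CPM in stretch libraries, and had a log2 fold change of -0.01 ± 0.37 (edgeR adjusted p = 0.982). The receptor gene Notch1 (chromosome 2, 26457902 to 26503822) had a log2 fold change of -0.12 ± 0.05 and did not pass (edgeR adjusted p = 0.0852), but passed without control replicate 4 (adjusted p = 0.0338) and with library sizes alone as scaling (adjusted p = 0.00635). Of 21 tested genes 5 rose, 5 fell and 11 did not pass (5 and 5 adjusted over the list alone). The 5 that rose were Jag1, Hes1, Rbpj, Maml2 and Maml1, and the 5 that fell were Nrarp, Lfng, Mfng, Rfng and Adam10. Maml1 and Maml2 lost their calls without stretch replicate 1 (edgeR adjusted p = 0.0579 and 0.0600). Nrarp, a feedback inhibitor of Notch, fell 1.91-fold, and the glycosyltransferase gene Mfng fell 1.58-fold, while Rbpj, the DNA-binding partner of Notch, rose 1.26-fold. Camera did not separate the list from other genes (adjusted p = 0.903).

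Among 20 flow-responsive and vasoactive genes, 4 rose, 8 fell and 8 did not pass (4 and 8 adjusted over the list alone; camera adjusted p = 0.639). Klf6 rose 1.44-fold together with Klf2, Edn1 and Ptgs2, and cyclooxygenase-1 (Ptgs1), the VEGF receptor Kdr and the angiopoietin receptor Tek fell 1.57-fold, 1.33-fold and 1.28-fold. Of 21 TGF-beta and BMP signalling genes, 4 rose, 9 fell and 8 did not pass (4 and 9 adjusted over the list alone). Tgfb1 rose 1.64-fold, whereas Bmp2 fell 1.68-fold, the coreceptor endoglin (Eng) 1.48-fold and the receptor Tgfbr2 1.46-fold. This list was not called by camera (adjusted p = 0.365) but moved on balance downward by fry (adjusted p = 0.0101; adjusted p = 0.608 with an estimated correlation). Angiocrine and angiogenic factors numbered 19, of which 7 rose, 3 fell and 9 did not pass (7 and 3 adjusted over the list alone; camera adjusted p = 0.288). Pdgfb rose 2.61-fold, the KIT ligand gene Kitl 2.07-fold and Sema6d 1.82-fold, and Wnt2, a growth signal from sinusoidal endothelium to hepatocytes, fell 2.14-fold.

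Extracellular matrix genes changed little: of 35, 1 rose, 5 fell and 29 did not pass, and 0 and 0 passed adjusted over the list alone (camera adjusted p = 0.658). Fibronectin (Fn1) had the single increase, 1.41-fold, and biglycan (Bgn), Lama5 and Mmp2 fell 1.53-fold, 1.38-fold and 1.34-fold, and Fbn1 and Col5a2 also fell. The edgeR calls of Fn1, Bgn, Lama5 and Mmp2 were lost when single libraries were left out. Without stretch replicate 1, 4 members of the list passed as lower, among them Bgn, Lama5 and Mmp2, so Fbn1 and Col5a2 did not both keep their calls. For Fn1 the edgeR adjusted p was 0.0851 without control replicate 2, 0.114 without control replicate 3, 0.0848 without stretch replicate 1 and 0.105 without stretch replicate 2. For Mmp2 the edgeR adjusted p was 0.0771 and 0.144 without control replicates 3 and 4 and 0.0780 and 0.121 without stretch replicates 2 and 4. Without control replicate 2 and without stretch replicate 4 the edgeR adjusted p was 0.0502 and 0.0520 for Bgn and 0.0613 and 0.0600 for Lama5.

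Markers of the sinusoidal endothelial phenotype were lower after stretch. Of 16, 10 fell, 1 rose and 5 did not pass (10 and 1 adjusted over the list alone). Besides Maf, the orphan receptor gene Gpr182 fell 2.42-fold, from 192 ± 26.25 to 79.3 ± 15.5 CPM, Oit3 fell 1.86-fold and the Fc receptor gene Fcgr2b fell 1.748-fold. Tfec was the 1 that rose. The list was lower by camera (adjusted p = 0.00671), but not with an estimated correlation (adjusted p = 0.491). Of 16 markers of continuous endothelium, the lining of other capillaries and large vessels, 1 rose, 1 fell and 14 did not pass (1 and 1 adjusted over the list alone; camera adjusted p = 0.436). These were the arterial ligand gene Efnb2, which rose 1.41-fold, and the transcription factor gene Sox18, which fell 1.99-fold. Interferon response genes were lower in part, with 10 of 22 lower, 0 higher and 12 that did not pass (10 and 0 adjusted over the list alone). Ifit3 fell 2.49-fold, Oasl2 1.95-fold, Gbp2 1.51-fold and the signalling gene Stat2 1.48-fold. The interferon list was called lower by camera (adjusted p = 0.00591; adjusted p = 0.608 with an estimated correlation).

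Cholesterol synthesis and uptake genes were mostly lower. Of 21 genes 20 fell, 0 rose and 1 did not pass (20 and 0 adjusted over the list alone), and the 1 was Srebf2, which encodes the regulator of the pathway, with a log2 fold change of -0.09. The cholesterol transporter gene Stard4 fell 1.87-fold, from 98.2 ± 6.53 to 52.6 ± 4.57 CPM, mevalonate kinase (Mvk) 1.78-fold and Dhcr7, the last enzyme of the pathway, 1.753-fold. Camera called the list lower (adjusted p = 2.98e-08; adjusted p = 0.429 with an estimated correlation).

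Several stress and metabolic lists were higher. Of 20 unfolded protein and amino acid stress response genes, 12 rose, 0 fell and 8 did not pass (12 and 0 adjusted over the list alone). The mitochondrial folate enzyme gene Mthfd2 rose 1.97-fold, the transcription factor gene Atf4 1.49-fold, asparagine synthetase (Asns) 1.47-fold and the chaperone gene Hspa5 1.31-fold (camera adjusted p = 0.00223; adjusted p = 0.347 with an estimated correlation). Of 15 heat shock genes, 8 rose, 1 fell (Hspa4l) and 6 did not pass (8 and 1 adjusted over the list alone). Hsp90aa1 rose 1.61-fold, Hspd1 1.575-fold, Hspa8 1.35-fold and Hsph1 1.248-fold (camera adjusted p = 0.00588; adjusted p = 0.347 with an estimated correlation). Of 22 glycolysis and hypoxia genes, 9 rose, 2 fell (Pfkfb4 and Ndrg1) and 11 did not pass (10 and 2 adjusted over the list alone), and 1 of the 2 decreases passed without stretch replicate 1. Hexokinase 2 (Hk2) rose 2.70-fold, the glucose transporter gene Slc2a1 1.93-fold, Pfkfb3 1.86-fold and Pfkp 1.45-fold. Camera called this list higher (adjusted p = 0.0161; adjusted p = 0.608 with an estimated correlation), but not without control replicate 4 (adjusted p = 0.0528) or without stretch replicate 1 (adjusted p = 0.0557), and the lowest over such fits was 0.00155. The glycolysis list also did not pass with the replicate block (camera adjusted p = 0.0556) or by fry (adjusted p = 0.0818).

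NRF2 targets, the antioxidant genes, and cell cycle genes showed no shared direction past the test. Of 20 NRF2 targets 6 rose, 2 fell and 12 did not pass (6 and 2 adjusted over the list alone; camera adjusted p = 0.228). Txnrd1, Srxn1 and Sqstm1 rose 1.42-fold, 1.36-fold and 1.35-fold, and Osgin1 and Nqo1 were the 2 that fell, Osgin1 by 1.24-fold. Of 28 cell cycle genes 2 rose, 6 fell and 20 did not pass (2 and 4 adjusted over the list alone). Cyclin D1 (Ccnd1) and Pcna rose 1.802-fold and 1.17-fold, and the proliferation marker Mki67 and the replication helicase gene Mcm4 fell 1.95-fold and 1.29-fold. The cell cycle list did not pass by camera (adjusted p = 0.103), and passed as lower without control replicate 2 (adjusted p = 0.0396) and without stretch replicate 2 (adjusted p = 0.0403), while over the 6 fits that each left out 1 library the adjusted p reached 0.259.

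Markers of other liver cell types were measured in the same libraries. Of 19 hepatocyte markers 14 rose, 0 fell and 5 did not pass (15 and 0 adjusted over the list alone). Without stretch replicate 1, 6 rose. Their summed level was 139, 116 and 164 CPM in control replicates 2, 3 and 4 and 1050, 238 and 232 CPM in stretch replicates 1, 2 and 4 (exact two-sided permutation p = 0.1, the smallest possible). Transferrin (Trf) rose by a log2 fold change of 2.28 ± 0.56, and by 1.22 without stretch replicate 1, and Cps1 and Fgb by 2.35 ± 0.62 and 2.51 ± 0.72. With robust dispersion the calls of Trf (edgeR adjusted p = 0.0789), Cps1 (edgeR adjusted p = 0.0657) and Fgb (edgeR adjusted p = 0.114) were lost, and with limma-voom those of Cps1 (adjusted p = 0.0979) and Fgb (adjusted p = 0.103). Cps1 and Fgb also lost theirs without control replicate 2 (edgeR adjusted p = 0.0639 and 0.0800) and without control replicate 3 (edgeR adjusted p = 0.0521 and 0.0714). Transthyretin (Ttr) rose 4.28-fold (SE of the log2 fold change 0.62), with a log2 fold change of 1.00 without stretch replicate 1, and its call was lost without stretch replicate 1 (edgeR adjusted p = 0.0509), without control replicate 2 (edgeR adjusted p = 0.0835) and without control replicate 3 (edgeR adjusted p = 0.0815), as well as with robust dispersion (edgeR adjusted p = 0.0805), with glmTreat (edgeR adjusted p = 0.0546) and with limma-voom (adjusted p = 0.107). The hepatocyte list was higher by camera (adjusted p = 0.00591; adjusted p = 0.608 with an estimated correlation) and did not pass by fry (adjusted p = 0.182).

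Of 15 Kupffer cell and macrophage markers 12 rose, 0 fell and 3 did not pass (14 and 0 adjusted over the list alone), and 11 rose without stretch replicate 1. Their summed level was 131, 130.2 and 112 CPM in control replicates 2, 3 and 4 and 201, 148 and 181 CPM in stretch replicates 1, 2 and 4. Marco, a scavenger receptor gene, rose from 0.26 ± 0.09 to 2.445 ± 1.68 CPM, lysozyme (Lyz2) from 15.5 ± 4.87 to 33.5 ± 2.64 CPM, and the complement genes C1qb and C1qa 3.35-fold and 5.73-fold. For Marco the log2 fold change was 3.25 ± 0.53 with all libraries and 2.54 without stretch replicate 1. Camera called the macrophage list higher (adjusted p = 0.000101; adjusted p = 0.429 with an estimated correlation).

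**Figure D3:**
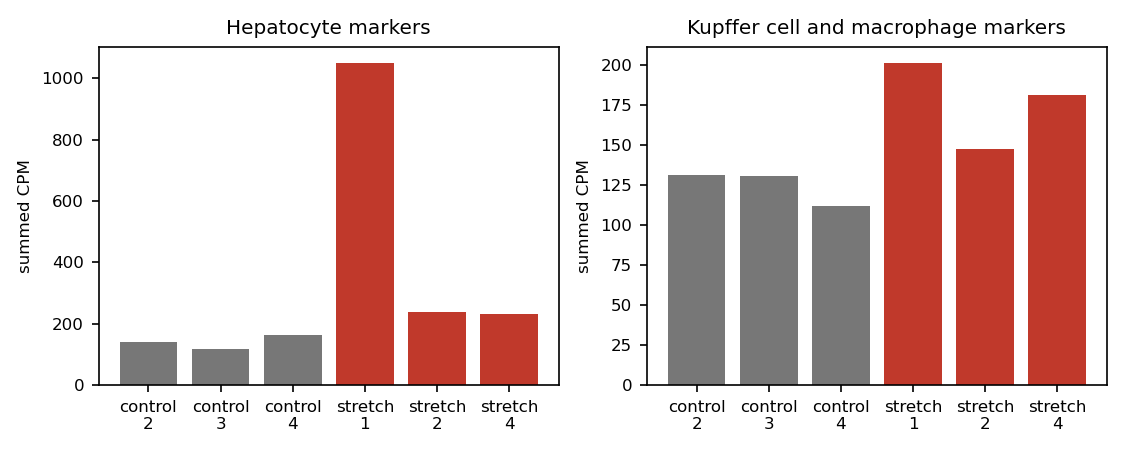
Summed CPM (TMM-scaled) of the tested hepatocyte markers (left) and of the tested Kupffer cell and macrophage markers (right) in each control library (grey bars) and stretch library (red bars). Hepatocyte markers reached 1050 in stretch replicate 1 and stayed between 116 and 238 in the other libraries.

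Of 13 cholangiocyte and mesothelial markers 6 rose, 0 fell and 7 did not pass (6 and 0 adjusted over the list alone). Osteopontin (Spp1) rose 2.38-fold, keratin 18 (Krt18) 1.89-fold, Sox9 1.748-fold and Epcam 1.68-fold. The list did not pass by camera (adjusted p = 0.0530), but passed without control replicate 4 (adjusted p = 0.0207), without stretch replicate 4 (adjusted p = 0.0149) and with library sizes alone as scaling (adjusted p = 0.0138), while over the 6 fits that each left out 1 library the adjusted p reached 0.173. Among 15 stellate cell and fibroblast markers 1 rose, 0 fell and 14 did not pass, and 0 and 0 passed adjusted over the list alone (camera adjusted p = 0.996). The 1 was the pericyte gene Rgs5, at 1.00 ± 0.28 CPM in control and 2.24 ± 1.01 CPM in stretch libraries. Its edgeR call was kept without stretch replicate 1 and lost without control replicates 2, 3 and 4 (adjusted p = 0.134, 0.0680 and 0.0687) and without stretch replicates 2 and 4 (adjusted p = 0.127 and 0.108). Col1a1 had a log2 fold change of -0.33 ± 0.16 (edgeR adjusted p = 0.130). Of the neutrophil, B cell, T cell and platelet markers 3 had enough counts to be tested and 0 passed with edgeR. Of these, the platelet genes Pf4 and Itga2b had log2 fold changes of 0.72 ± 0.28 (edgeR adjusted p = 0.0688) and -0.49 ± 0.20 (edgeR adjusted p = 0.0828). Pf4 passed with edgeR without stretch replicate 2 (adjusted p = 0.0273, up to 0.312 over the alternatives) and Itga2b with library sizes alone as scaling (adjusted p = 0.0442, up to 0.314). None of the erythroid markers had enough counts to be tested.

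Of 26 lists tested with camera, 13 passed, 10 higher and 3 lower, and 0 passed with an estimated correlation. With 3 libraries per group that setting has little power, so the 0 does not show that correlation between genes accounts for the 13. Members named only to list a count of 5 or fewer (such as Jam3, F8, Itga1 and Tfec), and Acta2 and Srebf2, were chosen after their values were seen. Actb, Actg1, Hspa8, Hsp90aa1, Ifit3, Iigp1, Cyp3a11 and the Serpina1 genes have near-identical copies in the genome, so their values are uncertain where the counting divided reads between copies.

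In the authors' deposited table, 5712 of 23336 genes had an adjusted p under 0.05, 2864 higher and 2848 lower after stretch. Among the genes tested here 5510 of these calls remained, and 5474 of them (99.3%) were also called here, all in the same direction. They made up 87.4% of the calls made here. The largest difference in log2 fold change between that table and the fit made here was 0.07, over called genes with a mean above 1 log2 CPM.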

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

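All alternatives were chosen before the data were examined, except counting list members without stretch replicate 1. No called gene changed direction under any alternative fit of the genes. Other scalings, filters and tools called between 6044 and 6390 genes, against 6261. With glmTreat, which tests against a minimum fold of 1.2, the count was 2537, with 1210 higher and 1327 lower, since smaller changes no longer pass. Leaving out 1 library gave between 4756 and 5895 calls, between 2348 and 3022 higher and between 2408 and 2873 lower. Of the 122 named genes 11 lost a call in at least 1 of these 6 fits: Cps1, Creb3l3, Cyp3a11, Fga, Fgb, Ttr, Bgn, Lama5, Fn1, Mmp2 and Rgs5. Robust dispersion ended 10 calls, limma-voom 9 and glmTreat 15.

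With the replicate block 5568 genes were called from 6 samples and 5558 from the samples numbered 2 and 4 alone. Libraries with any other number have no partner of the same number in the other group. Under the block those libraries add nothing to the estimated group difference. Both fits therefore compare the same libraries, those numbered 2 and 4, and are not separate checks. The deviations of same-numbered libraries from their group means correlated at r = 0.212 for number 2 and 0.114 for number 4 across genes, and 2 pairs are too few to show that the numbers pair the cultures. Under the replicate block Fn1 was not called (edgeR adjusted p = 0.0853 with 6 samples and 0.0857 with numbers 2 and 4 alone), nor was Cyp3a11 with numbers 2 and 4 alone (0.0897). The glycolysis and hypoxia list did not pass (adjusted p = 0.0556), and the log2 fold change of Hey1 was 0.36 with 6 samples and 0.36 with numbers 2 and 4 alone. No other call of a named gene or list changed under the block.

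Among genes that were not called, Fam38a changed sign with library size only (-0.055), and Hey1 with RLE factors (0.0037), DESeq2 (0.0032) and limma-voom (0.013). Leaving out 1 library moved Hey1 between -0.29 and 0.22. The cause was not tested, and Hey1 is near the limit of depth, at 0.57 CPM in control libraries.

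With an estimated correlation none of the 13 called lists passed: the camera adjusted p was 0.347 for chemokines and cytokines, NF-kB genes, immediate early genes, contractile and actin genes, the unfolded protein response and heat shock, 0.429 for mechanosensors, cholesterol synthesis and macrophage markers, 0.491 for sinusoidal endothelial markers, and 0.608 for interferon response, glycolysis and hepatocyte markers. The unfolded protein list lost its call with an estimated correlation of -0.028, below the preset 0.01, so correlation between its genes does not explain that loss. Heat shock, with an estimated correlation of 0.029, and immediate early genes, with 0.4, had the same adjusted p of 0.347. With an estimated correlation camera relies on the residual degrees of freedom, which are few for 6 libraries in 2 groups, and with the preset one it does not. Little power is left, so failing this test does not show that correlation between genes accounts for a list's result. With fry, adhesion (0.0233), coagulation (0.0209) and TGF-beta and BMP signalling (0.0101) passed, and glycolysis (0.0818) and hepatocyte markers (0.182) did not. The remaining called lists passed with fry, with adjusted p between 0.000681 for the unfolded protein response and 0.0296 for interferon response. Fry does not compare a list with other genes. With library size only, coagulation (0.0384) and cholangiocyte markers (0.0138) passed. The stellate list, which was not called, changed direction with fry (0.946), RLE factors (0.949) and no filter (0.922). The cause was not tested.

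Over the fits that left out 1 library, the camera adjusted p ranged from 0.611 to 0.929 for Notch, 0.425 to 0.810 for extracellular matrix, 0.0396 to 0.259 for cell cycle, 0.00155 to 0.0557 for glycolysis, 0.418 to 0.917 for stellate and 0.0149 to 0.173 for cholangiocyte lists. Glycolysis was the 1 of 13 called lists that lost its call there. Without stretch replicate 1, hepatocyte markers called higher went from 14 to 6, and members called lower from 2 to 1 among mechanosensors and from 2 to 1 among glycolysis genes. The cause was not tested. The alternative for the mitochondrial share was not run, as 0 mitochondrial genes are listed.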

Other observations

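All tests in this part except the count over other splits of the samples were chosen after the result was seen. Feedback inhibitors of ERK signalling, the growth factor cascade that induces immediate early genes, were prominent among the strongest increases: Spry4 had a log2 fold change of 2.60 ± 0.20, Errfi1 of 1.97 ± 0.13 and Dusp5 of 1.42 ± 0.14. A broader set, not limited to inhibitors of ERK itself, was written after these genes were seen, and of its 19 tested members 11 rose and 0 fell. Without the genes that prompted the set, 7 of 15 rose and 0 fell, and camera still placed them above other genes (adjusted p = 0.00143; adjusted p = 0.293 with an estimated correlation). The 7 were Spred1, Dusp6, Dusp7, Dusp8, Dusp10, Phlda1 and Ier3. Spry1, Spred2, Dusp4, Etv4 and Etv5 were among those that did not pass, so the test does not show that ERK feedback rose as a whole. Ligands of the ErbB and PDGF receptors rose in part: of 11 tested, 6 rose and 1 fell. Hbegf had a log2 fold change of 2.16 ± 0.11 and Pdgfa of 2.20 ± 0.16, and Nrg1, the 1 that fell, of -1.04 ± 0.26. The 8 members left without the prompting genes did not pass (camera adjusted p = 0.796).

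Ribosome biogenesis genes, which make and assemble ribosomes in the nucleolus, rose almost throughout. Of 47 genes 45 rose and 2 fell (Ubtf and Imp3), with a median log2 fold change of 0.55, and 44 rose and 1 fell without stretch replicate 1, where Ubtf no longer passed (edgeR adjusted p = 0.171). Camera gave an adjusted p = 4.36e-17, and adjusted p = 0.293 with an estimated correlation, but the list was written after genes of this kind were seen to rise and none of the 47 was removed, so the test decides nothing beyond the counts. FOXO target genes, which growth signalling represses, fell in part, with Sesn1 at -1.24 and Ccng2 at -1.03 (log2 fold change), but without the prompting genes 8 of 19 fell, 3 rose and the set did not pass (camera adjusted p = 0.148). The clock set, prompted by Dbp and Per3, gave no common direction (camera adjusted p = 0.852).

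Of the 10 splits of the 6 samples into 3 and 3, 1, the real one, called as many as 6261 genes, and the highest of the others called 0. With 10 splits a share under 0.05 is out of reach. Each other split also mixes control and stretch libraries in both groups. The group difference then adds to the spread within groups, so few calls were likely in advance and the 0 is no measure of chance.

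Hepatocyte markers were higher in the stretch group although the cells had been purified with antibody-coated magnetic beads. Across 19 markers, stretch replicate 1 exceeded the other stretch libraries by a median of 2.1 on the log2 scale (interquartile range 1.68 to 2.29). The markers did not move alike: Cyp2e1 exceeded by 0.36, Ass1 by 0.733 and Tat by 1.16, and Cyp2e1 in stretch replicates 2 and 4 was at -0.341 relative to control. Albumin (Alb) reached 232.5 CPM there, against 54.4 and 45.0 CPM in stretch replicates 2 and 4 (edgeR adjusted p = 0.0504 without stretch replicate 1), and Trf 261 against 62.6 and 60.0 CPM. Hepatocyte cells or RNA in that culture is a candidate explanation, but this excess is what prompted the test, and induction of these transcripts in that culture would give it too, so the origin stays open. In stretch replicates 2 and 4 the median was 0.66 above control (0.485 to 0.877) and 6 markers were called without stretch replicate 1, which leaves open whether stretch raises these transcripts in every culture, since a smaller carryover in those libraries cannot be told apart from it.

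Chemokine and NF-kB genes rose beside macrophage markers, which control replicates 2, 3 and 4 already held at 131, 130.2 and 112 CPM in sum after the bead purification. Most of that sum came from other members than Marco, C1qa, C1qb and Lyz2, whose control means were 0.26, 0.20, 0.72 and 15.5 CPM. The markers did not move alike: their median log2 fold change was 1.22 and that of Marco 3.25, while the mean sum went from 124 to 177 CPM. Ccl2, Ccl7, Cxcl2 and Csf1 together rose by 2120 CPM, 40.5 times the 52.3 CPM by which 15 macrophage markers rose (34.6 to 66.8 over the stretch libraries), but how much chemokine RNA a macrophage holds relative to these markers was not measured, so their source stays open. Nfkbia rose from 136 ± 9.25 to 260 ± 21.0 CPM in the same libraries, with the same limit. Tnf, Il1a, Ccl3, Ccl9 and Cd40 together rose by 22 CPM, 0.421 times the macrophage rise (0.327 to 0.592), but genes this scarce could hardly exceed the markers, so this value does not show where they come from. Macrophage cells or RNA stays a candidate explanation, and a direct response of the endothelial cells, or a response to factors from macrophages in the culture, was not tested.

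Cyp11a1, a steroid synthesis enzyme, had 0, 609 and 326 counts in control replicates 2, 3 and 4 and 2, 15 and 2 in stretch replicates 1, 2 and 4, a ratio of 54.3 (95% exact interval 34.5 to 90.5, counting error only). The other adrenal cortex markers reached 93.3% of its CPM above the stretch libraries (84.8 to 102, counting error only), or 40.9% without Akr1b7, whose counts do not follow those of Cyp11a1. Taken singly, control replicates 3 and 4 gave 38.9% and 202%, or 47.3% and 28.0% without Akr1b7. Hsd3b1 followed with 2, 139 and 64 counts in control replicates 2, 3 and 4, Cyp11b1 with 0, 144 and 51, Nr5a1 with 2, 109 and 28 and Mc2r with 0, 25 and 16. Akr1cl and Prss35 did so too, and each of these genes had at most 10 counts in any stretch library. Cyp21a1, another adrenal enzyme, went otherwise, with 2, 25 and 13 in these controls and 39, 2 and 9 in the stretch libraries. Adrenal cortex carried into control cultures 3 and 4 is a candidate explanation for Cyp11a1 that leaves the counts of Akr1b7 and Cyp21a1 in stretch libraries unexplained. Ctsq, with 73, 427 and 523 counts in the same libraries, did not keep a fixed ratio to Cyp11a1 (chi-square p = 1.18e-32, counting error only), but separate cultures can differ beyond counting error, so a shared source stays open. Other trophoblast markers reached 1.93% of its CPM (0.156 to 3.71, counting error only). How much RNA of these markers trophoblast holds relative to Ctsq was not measured, so this argues only against trophoblast tissue rich in them. The source of the Ctsq counts stays open, and an effect of stretch on the gene itself stays open as untested.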
